A study of Mus musculus with 12 samples.

How the data were processed

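Nucleus accumbens of mouse brain was profiled by chromatin immunoprecipitation and sequencing with an antibody against the histone variant H2A.Z, in 12 samples that fall into 4 conditions of 3 samples each. Conditions were taken from the sample titles: saline then saline (SS), saline then cocaine (SC), cocaine then saline (CS) and cocaine then cocaine (CC). The labels describe the SC, CS and CC lists as acute, withdrawal and challenge. They give no dose, interval, sex or batch. Total histone H3 was profiled alongside, according to the design text of the series, and the H3 libraries were not analysed here. The labels call the library source transcriptomic, while the molecule is genomic DNA and the assay is immunoprecipitated chromatin.

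The data analysed were 4 annotated peak lists deposited by the authors, 1 per condition, named by all 3 samples of that condition. Whether a list was called on pooled reads or merged from calls per sample is not given in the sources used here. The mm10 build and the tools cutadapt, HISAT, SAMtools and MACS2 come from the submitters' processing notes, and versions, peak-calling settings and the control library are not given in the sources used here. Each peak carries a fold enrichment, a ratio over background computed by the authors, per the file headers. Each peak also carries a q-value on a linear scale, per the file headers. The authors deposited a region class, an assigned gene and a signed distance with each annotated peak. On testing, the distance equalled the middle of the peak minus the transcription start site (TSS), within 1 bp. Starts and ends are printed as the authors' lists give them, since whether they count from 0 or 1 is not stated.

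Each peak is assigned to 1 gene by the authors, so a promoter shared by a pair of divergent genes can change its name from list to list. For that reason the number of genes held by 1 list only is also given after removing genes whose peak overlaps any peak of the other list. Of 16758 gene names in the lists, 14941 (89.2%) matched a symbol in the RefSeq table of assembly GRCm38.p6, which lists 21900 protein-coding genes. No coordinates were taken from that table. No column held values of samples outside the series.

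Lists were compared by overlap of at least 1 bp with bedtools 2.31.1. A gene was counted as having a promoter peak when a peak middle lay within 1000 bp of its TSS. SS peaks were sorted by fold enrichment into 5 equal groups, and the share of each group overlapped in another list was computed with the area under the ROC curve of SS fold enrichment for being overlapped. The authors' fold enrichment was used to describe and rank peaks within a list, never to measure a change between lists. Shares carry 95% exact binomial (Clopper-Pearson) intervals, which cover the counting of peaks or genes only. Because each condition has 1 list without values per sample, there is no spread between samples, no test between conditions and no p-value. Sequencing depth per sample was not analysed here.

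A total of 23 gene lists were fixed before the data were examined: markers of D1, D2 and all medium spiny neurons, of striatal interneurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia and endothelium, immediate early genes, glutamate receptors, GABA receptors and synthesis, dopamine and cAMP signalling, MAPK and CREB signalling, postsynaptic scaffolds, presynaptic release machinery, voltage-gated channels, H2A.Z genes and exchange complexes, cytosolic ribosomal proteins, the mitochondrial respiratory chain, proteasome subunits, a list labelled silent developmental transcription factors, and olfactory receptors. The list labelled silent was drawn by name from the Hox, Pax, Gata, Tbx and Nkx genes. Expression was not measured here, so silence of its members in striatum is presumed. For each list, the share of its SS promoter genes that also had a promoter peak in another list was placed among 10000 random sets of SS promoter genes of the same size, matched on SS fold enrichment in 10 strength classes (seed 1). The resulting percentile describes these lists and is not a p-value. Percentiles were read for the 21 lists with at least 4 SS promoter genes, and those below 2.5 or above 97.5 were counted.

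Genes named in the text follow a rule fixed in advance. Against SS, these are the 10 genes with the strongest promoter peak in SS and neither a promoter peak nor an overlapping peak in the other list, and the 10 strongest in the opposite direction. For CC against SC and CC against CS they are the 5 strongest in each direction. Added to these are the 10 strongest SS genes held in all 4 lists, the members of each fixed list with the strongest SS peak, and Anp32e, Drd1, Drd2, Fos, Fosb, Egr1, Arc, Npas4, Nr4a1, Bdnf, Penk, Pdyn and Tac1. Pseudogenes, clone names and names starting Gm or ending Rik were skipped, and a few genes that the rule or the lists would name are not reported here. Other list members and the Y-linked genes are named where a count is small, and were chosen after their values were seen.

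The computations were tested on simulated data: with peaks planted over the 24655 SS peaks, 100% of planted peaks were found, the area under the ROC curve was 1 for retention set by strength and 0.496 for random retention. Retention was also simulated over the 13585 SS promoter genes, at the same rate for all genes except a planted set made to be poorly held. That set fell at percentile 0, and 4.5% of unselected sets fell outside the 2.5 and 97.5 percentiles. The simulated rate did not depend on strength, unlike the overlap seen in CS, so the matching on strength was not put to a test. These simulations check the computation only. The 19 alternatives fixed in advance covered a stricter threshold of 5 for −log10 of the q-value, lists cut to equal length, overlap of 50% of the shorter peak or within 1000 bp, a promoter window of 3000 bp, chromosomes 1 to 19 and X with peaks closer than 1000 bp merged, strength taken from the q-value and shares weighted by width. A further 6 were added after the data were seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.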

Results

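H2A.Z is a variant of histone H2A found around the start sites of genes, and its exchange at promoters has been linked to gene activity in neurons. Peaks of H2A.Z were compared in the nucleus accumbens, a ventral striatal region of the reward circuit, of mice under 4 conditions named by an earlier and a later treatment: saline-saline (SS), saline-cocaine (SC), cocaine-saline (CS) and cocaine-cocaine (CC). Each condition comprised 3 samples and was represented by 1 peak list, so no value below has a replicate error, and intervals cover the counting of peaks or genes only. Sequencing depth was not analysed here; the size of a list is given as its number of peaks and the sequence they cover. The comparisons ask what a first cocaine exposure, a cocaine history followed by saline, and cocaine after such a history go with in the H2A.Z peak set. Coordinates are on mm10.

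Promoters held most H2A.Z peaks in every list. The SS list held 24655 peaks covering 19.7 Mb and the SC list 23170 peaks covering 18.0 Mb, while the CS list held 6417 peaks covering 0.837 Mb and the CC list 4827 peaks covering 0.614 Mb. Peaks within 1000 bp of a TSS made up 62.3% of the SS list (95% interval 61.7 to 62.9%), 63.4% of SC (62.8 to 64.0%), 79.5% of CS (78.5 to 80.5%) and 80.5% of CC (79.3 to 81.6%). Gene bodies held 11.7% of SS and 14.1% of SC peaks against 5.11% of CS and 4.52% of CC peaks, and intergenic sequence held 21.5%, 18.1%, 12% and 11.4%. The order of the promoter shares depended on which peaks were counted: among peaks with −log10 q of at least 5 they were 63.3%, 64.4%, 61% and 60.6%, and among the 4827 strongest peaks SS had 93.6% and SC 93.1%. Genes with a promoter peak numbered 13585 in SS, 12948 in SC, 4320 in CS and 3394 in CC, or 53.4%, 50.9%, 17.2% and 13.5% of protein-coding genes when only those were counted. The peaks themselves differed along the same division: the median width was 734 bp in SS and 727 bp in SC against 110 bp in CS and 107 bp in CC, and the shortest peak was 321, 315, 69 and 67 bp. The highest q-value listed was 0.000544 in SS, 0.000572 in SC, 0.0510 in CS and 0.0625 in CC. Peaks with −log10 q of at least 5 were 97.7% of SS, 97.9% of SC, 17.8% of CS and 19.6% of CC peaks.

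**Figure D1:**
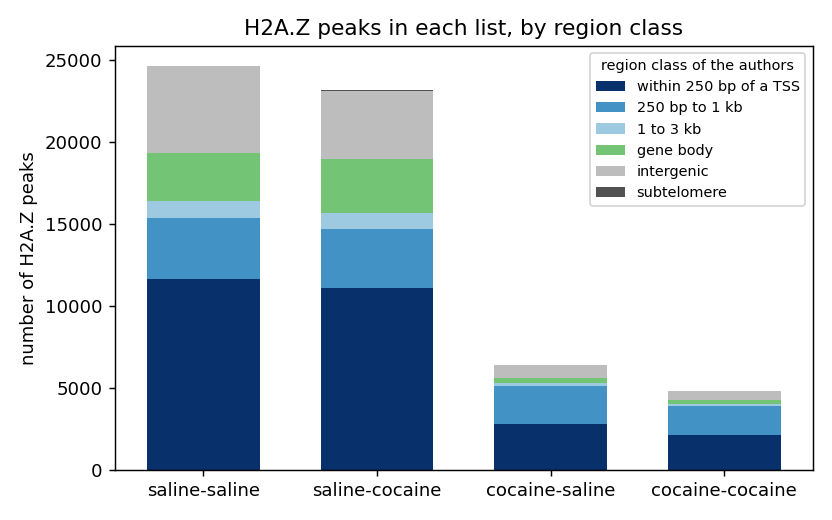
Number of H2A.Z peaks in each of the 4 lists (vertical axis), stacked by the region class the authors gave each peak; each bar is 1 list. The saline-saline and saline-cocaine bars reach 24655 and 23170 peaks, and the cocaine-saline and cocaine-cocaine bars 6417 and 4827.

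A core of genes carried a promoter peak under all 4 conditions. These were 1586 genes, 11.7% of the SS promoter genes. The strongest of them in SS were Inpp5f, Selenon, Nt5m, the nuclear exporter Xpo4, the signalling kinase Map3k7, the peptide-amidating enzyme Pam, Cnih1, Ttc14, March8 and the Polycomb component Pcgf6, with authors' fold enrichments of 13.1 to 14.3 in SS. At Inpp5f the fold enrichment was 14.3 in SS, 15.4 in SC, 4.35 in CS and 6.16 in CC, where the folds of different lists are not on a common scale. The SS peak of Inpp5f spanned chromosome 7, 128611319 to 128612148. Pam carried its CS peak at another start site (chromosome 1, 98095242 to 98095312) than its SS peak (97976622 to 97977561). By contrast 6930 genes (51.0% of SS promoter genes) had promoter peaks in both SS and SC and none in CS or CC, and 90 genes had them in CS and CC and in neither SS nor SC.

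The first comparison, SC against SS, concerns a first cocaine exposure without a history. Most promoters carried H2A.Z in both lists: 11987 genes, 88.2% of the SS promoter genes, also had a promoter peak in SC. Drd2, the D2 dopamine receptor gene, was among them (fold enrichment 10.9 in SS, chromosome 9, 49340153 to 49340932, and 13.6 in SC), as were the opioid peptide gene Penk (7.65 and 11.4) and the substance P precursor Tac1 (3.65 and 3.79). Drd1, the D1 dopamine receptor gene, had a promoter peak in SS alone (3.76, chromosome 13, 54055015 to 54055758), and so did the neurotrophin gene Bdnf (3.49, chromosome 2, 109673790 to 109674360) and the dynorphin precursor Pdyn (3.48, chromosome 2, 129699246 to 129700180). These 3 peaks lay in the lower part of the SS range, whose median was 4.34. Among activity-induced genes Fos (2.93 in SS, 3.04 in SC), Fosb (4.20, 4.22), Egr1 (6.58, 7.84), Arc (3.53, 4.64) and Nr4a1 (5.62, 5.89) had promoter peaks in both, and Npas4 had none in any of the 4 lists.

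Peaks present in 1 of these lists only were mostly weak: the median fold enrichment was 3.37 for SS peaks with no overlapping SC peak (lower quartile of all SS peaks 3.43) and 3.20 for SC peaks with no overlapping SS peak (lower quartile of all SC peaks 3.44). With a promoter peak in SS, none in SC and no overlapping SC peak there were 1166 genes, the strongest of them including the replication origin factor Orc1 (8.08, chromosome 4, 108579341 to 108580125), the pro-apoptotic Pmaip1 (7.10), the mitochondrial ribosomal gene Mrpl15 (6.68), the prokineticin receptor Prokr1 (6.64), Trim58 (6.09), the mitotic ubiquitin enzyme Ube2c (6.09), Phlda2 (6.05), Nek5 (6.04) and Strip2 (6.04). Orc1, Pmaip1 and Strip2 nevertheless had promoter peaks in both CS and CC, and Nek5 had one in CS. In the other direction 516 genes had a promoter peak in SC with neither a promoter peak nor an overlapping peak in SS, led by Hoxa2 (7.86, chromosome 6, 52164172 to 52164623), the RNA helicase Ddx3x (7.38, chromosome X, 13281075 to 13281977), Bex1 (7.37), the ciliary neurotrophic factor receptor Cntfr (7.08), Stk31 (6.60), the autophagy gene Wdr45 (6.50), Nudt11 (6.30), Rsrc2 (6.17), Nudt10 (6.01) and Fam3a (6.01). Of these 10, Ddx3x, Bex1, Wdr45, Nudt11, Nudt10 and Fam3a lie on chromosome X. Chromosome X held 98 of the 516 genes (19%) against 2.79% of all SC promoter genes, and 40 of the 1166 SS-only genes (3.43%) against 2.24% of all SS promoter genes. Across peaks, 38.4% of SC peaks on chromosome X had no overlapping SS peak, against 13.7 to 25.2% on the autosomes. Promoter peaks of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) stood in SC and none in SS, while chromosome Y carried 11 peaks in SC and 9 in SS in all.

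**Figure D2:**
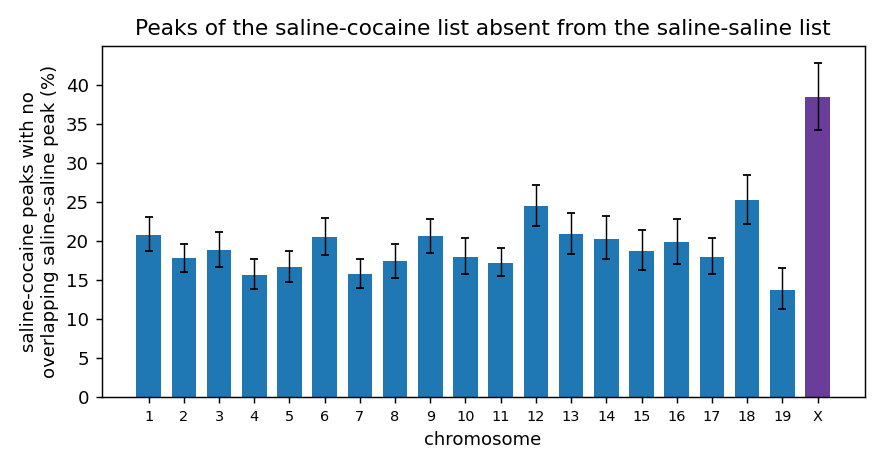
Share of saline-cocaine peaks with no overlapping saline-saline peak (vertical axis, percent) on each chromosome (horizontal axis), with 95% exact binomial intervals as error bars that cover the counting of peaks. Chromosome X stands at 38.4%, and the autosomes lie between 13.7 and 25.2%.

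Promoter peaks of neuronal and housekeeping genes were largely held in SC. All 26 voltage-gated channel genes with an SS promoter peak also had one in SC (percentile 99.6 among matched random sets), including Hcn2 (11 in SS) and Cacnb4 (10.3). Of 49 respiratory chain genes 48 were held (percentile 99.5), with Atp5a1 (10.2) and Atp5j (9.29) the strongest. With peak lists of equal length neither passed the upper limit for gene lists (12 of 13 channel genes held, percentile 85, and 4 of 5 respiratory chain genes, 37.8), and neither could have, since all genes held would give 97.3 and 79.3. The respiratory chain list also fell under that limit when an overlapping peak counted as held, an alternative added later. Promoter peaks were also held at 57 of 63 ribosomal protein genes, 29 of 30 proteasome genes, 24 of 24 MAPK and CREB genes, 19 of 19 postsynaptic scaffold genes, 16 of 16 presynaptic genes, 12 of 12 pan medium spiny neuron genes, 20 of 22 immediate early genes, 19 of 20 glutamate receptor genes, 13 of 15 GABA genes, 18 of 20 dopamine and cAMP genes and 16 of 17 genes of H2A.Z and its exchange complexes. With all peaks only 8 of the 21 lists could pass the upper limit in SC. Fully held, the MAPK and CREB, postsynaptic, presynaptic and pan medium spiny neuron lists could reach no more than 94.5, 91.4, 96.6 and 92.4. Passing the limit therefore does not set channel and respiratory chain genes apart from those lists. Cell type markers were held in 6 of 8 cases for D1 neurons, 4 of 5 for D2 neurons, 5 of 9 for interneurons (percentile 3.27), 5 of 7 for astrocytes, 5 of 6 for oligodendrocytes, 2 of 4 for their precursors and 3 of 4 for endothelium. Of the 40 developmental transcription factor genes presumed silent that had an SS promoter peak, 34 were held. Microglial markers had an SS promoter peak at 1 of 11 genes, and olfactory receptors at 3 of 1106 (Olfr94 held in SC).

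At the level of peaks, 75.7% of SS peaks overlapped an SC peak (75.2 to 76.2%) and 80.8% of SC peaks overlapped an SS peak (80.3 to 81.3%). Overlap followed strength: of the 5 strength groups of SS peaks, the weakest was overlapped in 43.6% and the strongest in 4929 of 4931 peaks, and the area under the ROC curve was 0.839 (0.834 to 0.844). By name alone, without the condition on overlap, 1598 genes were in SS only and 961 in SC only. The lists hold no values per sample, so these differences were not tested.

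The second comparison, CS against SS, concerns a cocaine history followed by saline. Promoter peaks were found at fewer genes in CS: 3914 genes, 28.8% of the SS promoter genes, were held. Genes whose strongest SS peaks had no counterpart in CS included BC005561 (16.4, chromosome 5, 104508258 to 104508972), the kinase Nek9 (15.8, chromosome 12, 85338777 to 85339628), the small GTPase Rab24 (15.0), the TFIID subunit Taf10 (14.9), Selenoi (14.8), the actin-related Actr2 (14.6), the exon junction factor Casc3 (14.5), the H2A.Z exchange ATPase Ep400 (14.4, chromosome 5, 110769964 to 110770804), Zc3h18 (14.3) and the endocytic adaptor Epn1 (14.3). All 10 had a promoter peak in SC, with fold enrichments between 13.6 and 17.9. In total 9671 SS promoter genes had none in CS, 9412 of them without any overlapping CS peak.

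The number of genes with a promoter peak in CS and none of that name in SS depended on the length of the lists. It was 406 with all peaks, 2417 with each list cut to its 4827 strongest peaks and 53 at −log10 q of at least 5. Of the 406 genes, 49 had no overlapping SS peak. They were led by the small nucleolar RNA gene Snord37 (9.71, chromosome 10, 81178135 to 81178240), the melatonin synthesis gene Asmt (7.70), Fkbp14 (5.08), the thiopurine methyltransferase gene Tpmt (4.98), Mettl9 (4.91), the histone H2B gene Hist1h2bn (4.84), Ccdc148 (4.69), Nol6 (4.68), Art3 (4.68) and the Y-linked Uty (4.68). Snord37, Asmt, Fkbp14 and Mettl9 also had promoter peaks in CC, and Mettl9, Nol6, Art3 and Uty had them in SC. The SC peak of Art3 (chromosome 5, 92402618 to 92402935) lay at another start site than its CS peak (92332561 to 92332678).

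In CS the lists below the 2.5 percentile of matched random sets were pan medium spiny neuron genes, immediate early genes and developmental transcription factors presumed silent. Only 14 of the 21 lists could fall below that limit in CS. None of the 8 D1 marker genes (percentile 5.22), 5 D2 marker genes (11.3), 12 pan medium spiny neuron genes (percentile 1.29) or 9 interneuron markers (percentile 4.35) with an SS promoter peak had one in CS, although Drd2 (10.9), Foxp1 (10.8), Gnal (11.2), Lhx8 (11.5) and Sfxn1 (10.7) were strong in SS. With none held, each of these lists stood at the lowest percentile open to it. Passing the limit therefore does not set pan medium spiny neuron genes apart from the other marker lists. Of 22 immediate early genes only Fosb was held (percentile 0.59, and 11.8 with lists of equal length; 4.95, chromosome 7, 19310123 to 19310219), while Nr4a2 (10.5 in SS), Ier5 (8.79) and Nptx2 (8.38) were not. Among 26 channel genes Cacna1a and Scn1a were held (percentile 3.08), among 20 glutamate receptor genes Gria4 and Grin2d (9.62), among 15 GABA genes 1 (7.13), among 20 dopamine and cAMP genes Ddc and Prkacb (3.66), and among 19 postsynaptic genes Dlgap3 and Dlgap4 (4.71). The presynaptic list had 5 of 16 held (percentile 69.0), with Cplx1, Rims2, Stx1a and Syn3 among them, and 5 of 24 MAPK and CREB genes were held (percentile 12.5). Developmental transcription factors presumed silent, such as Tbx18 (11.3 in SS), Tbx15 (10.6) and Hoxd1 (10.6), were absent, with Hoxa7 the only 1 of 40 held, against 29.0% in random sets of the same strength (percentile 0). Housekeeping lists were held within the range of random sets: 23 of 63 ribosomal protein genes (Rpl14 4.68; percentile 91.2), 15 of 49 respiratory chain genes (Cox5a 6.02; percentile 42.6) and 14 of 30 proteasome genes (Psma4 6.38; percentile 86.0). The H2A.Z list had 7 of 17 held (percentile 80.2): Anp32e, the chaperone that removes H2A.Z (4.55, chromosome 3, 95930225 to 95930307), Dmap1, Kat5, Morf4l1, Ruvbl1, Srcap and Trrap. No astrocyte (7), oligodendrocyte (6), precursor (4) or olfactory receptor (3) gene of SS was held, and endothelial Esam and Kdr were held among 4.

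**Figure D3:**
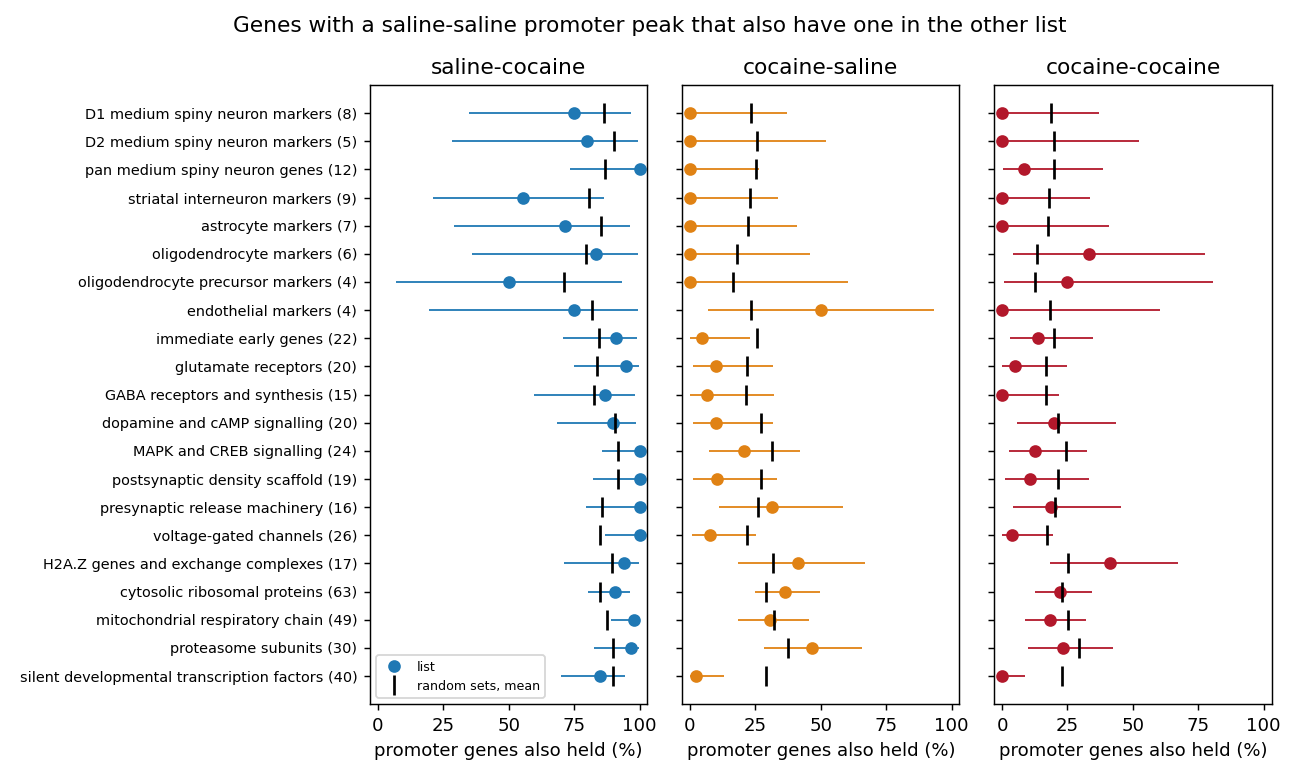
Percent of the genes of each fixed list with a saline-saline promoter peak (number in brackets) that also had one in the saline-cocaine, cocaine-saline or cocaine-cocaine list; points are the lists, horizontal lines 95% exact binomial intervals and vertical ticks the mean of 10000 random gene sets matched on peak strength. The list labelled silent developmental transcription factors, whose silence is presumed, stands at 85%, 2.5% and 0%, against tick values of 89.8%, 29.0% and 22.9%.

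Across the genome 20.3% of SS peaks overlapped a CS peak (19.8 to 20.8%), whereas 92.3% of CS peaks lay on an SS peak (91.6 to 92.9%). Proximal promoter peaks of SS were overlapped in 29.6%, gene body peaks in 7.13% and intergenic peaks in 9.29%. From the weakest to the strongest of the 5 groups of SS peaks the share was 4.50%, 6.43%, 22.1%, 40.8% and 27.6%, so the strongest group (26.4 to 28.9%) was overlapped less often than the fourth (39.4 to 42.2%). Middles of CS promoter peaks lay off the start site more often: 20.0% were within 100 bp of the TSS against 46.7% in SS. Between 500 and 200 bp upstream lay 25.3% of CS and 7.85% of SS middles. Median peak width was 110 bp in CS and 734 bp in SS, so a shift of H2A.Z cannot be told apart from narrower calls. CS differed from SS in its shortest peak (69 against 321 bp) and its highest q-value, and with only peaks of −log10 q of at least 5 in both lists the overlapped share of SS peaks was 3.49%.

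**Figure D4:**
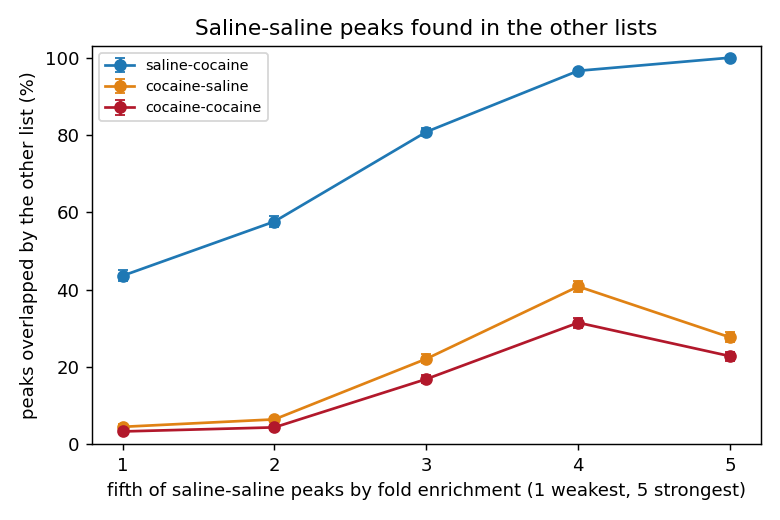
Share of saline-saline peaks overlapped by a peak of the saline-cocaine, cocaine-saline or cocaine-cocaine list (vertical axis, percent), for 5 equal groups of saline-saline peaks from the weakest (1) to the strongest (5) by the authors' fold enrichment; error bars are 95% exact binomial intervals. The saline-cocaine line rises from 43.6% in group 1 to 96.6% in group 4 and 4929 of 4931 peaks in group 5, and both other lines are highest in group 4, at 40.8% and 31.4%.

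The third comparison, CC against SS, concerns cocaine given after a cocaine history. Promoter peaks were held at 3084 genes, 22.7% of the SS promoter genes. The strongest SS promoter peaks with none in CC were those of Nek9 (15.8), the heparan sulphate synthesis gene Ext2 (15.3, chromosome 2, 93822038 to 93822830), Rab24 (15.0), Taf10 (14.9), Selenoi (14.8), Actr2 (14.6), the DNA damage checkpoint gene Topbp1 (14.5, chromosome 9, 103304781 to 103305774), Casc3 (14.5), Ep400 (14.4) and Zc3h18 (14.3). Ext2 and Topbp1 had promoter peaks in CS, and the other 8 had none there either. With a promoter peak in SS and none in CC there were 10501 genes, 10279 of them without an overlapping CC peak.

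In the other direction 310 genes had a CC promoter peak and none of that name in SS (2364 with lists of equal length), and 31 of the 310 had no overlapping SS peak. Snord37 (8.57, chromosome 10, 81178138 to 81178231) and Asmt (5.80) led again, followed by the splicing regulator Ptbp3 (5.50), Txndc12 (5.22), Gmfg (5.11), the class I histocompatibility gene H2-Q5 (5.08), Pigl (5.04), Tgds (4.83), the adaptor gene Gab1 (4.67) and Zc3h6 (4.46). H2-Q5 and Gab1 had promoter peaks in SC.

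In CC the lists below the 2.5 percentile were voltage-gated channels and developmental transcription factors presumed silent. Only 12 of the 21 lists could fall below that limit in CC. Lists with no member held, such as GABA genes and D1, D2 and interneuron markers, stood at the lowest percentile open to them. Voltage-gated channels kept Cacnb4 alone among 26 genes (4.07; percentile 2.25, and 9.92 with lists of equal length), GABA genes none of 15 (percentile 2.80), glutamate receptors Grik1 alone of 20 (percentile 7.58), and no marker of D1 neurons (8 genes, percentile 8.91), D2 neurons (5, 16.4) or interneurons (9, 7.91) was held. Pan medium spiny neuron genes kept Gnal (5.38), which couples dopamine and adenosine receptors to adenylyl cyclase in striatum, as the only 1 of 12 (percentile 17.2). Dopamine and cAMP genes were held in 4 of 20 cases (Gnal, Pde4b, Prkacb and Prkar2a; percentile 46.3). Immediate early genes kept Egr2, Klf2 and Nr4a2 of 22 (percentile 24.0), a set that does not include the Fosb of CS. Held too were 3 of 24 MAPK and CREB genes (percentile 8.16), Dlg2 and Dlgap3 of 19 postsynaptic genes (12.3), and Pclo, Stx1a and Vamp1 of 16 presynaptic genes (45.7). None of the 40 developmental transcription factors presumed silent was held, against 22.9% in matched random sets (percentile 0). Ribosomal protein genes were held in 14 of 63 cases (percentile 46.6), respiratory chain genes in 9 of 49 (13.4) and proteasome genes in 7 of 30 (23.7). The H2A.Z list was held in 7 of 17 cases (percentile 92.6): Actl6a, Actr6, Dmap1, H2afv, Ino80, Kat5 and Srcap, with Anp32e absent. Among other cells of the tissue the oligodendrocyte genes Cnp and Olig1 (of 6) and the precursor gene Lhfpl3 (of 4) were held, and no astrocyte (7), endothelial (4) or olfactory receptor (3) gene was.

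Of SS peaks, 15.7% overlapped a CC peak (15.3 to 16.2%), and 92.9% of CC peaks lay on an SS peak (92.2 to 93.6%). The share was 3.31%, 4.36%, 16.9%, 31.4% and 22.8% from the weakest to the strongest SS group. Middles of CC promoter peaks lay within 100 bp of the TSS in 20.8% and 500 to 200 bp upstream in 24.1%. These too are middles of narrower peaks (median width 107 bp in CC, 734 bp in SS). CC differed from SS in its shortest peak (67 against 321 bp), and with only peaks of −log10 q of at least 5 the overlapped share was 2.94%.

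**Figure D5:**
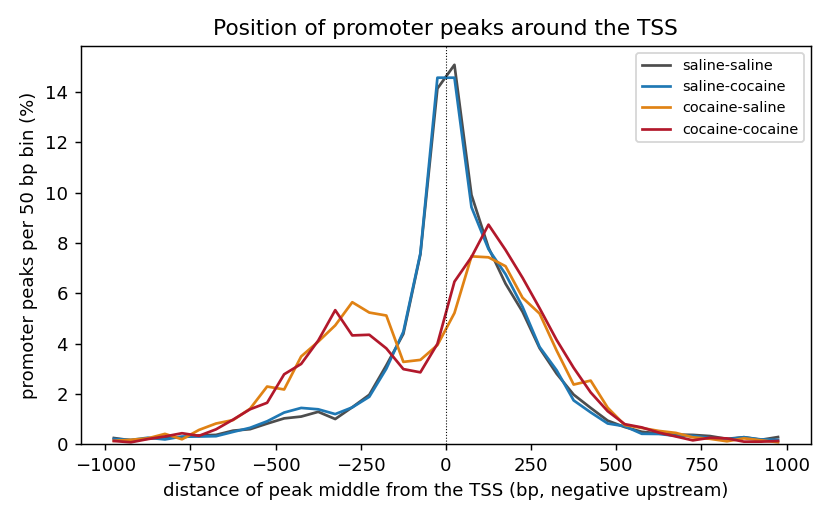
Position of the middle of promoter peaks relative to the transcription start site (horizontal axis, bp, negative upstream) as percent of each list's promoter peaks per 50 bp bin (vertical axis). The saline-saline and saline-cocaine lines peak at the start site, with 46.7% and 46.2% of promoter peaks within 100 bp, and the cocaine-saline and cocaine-cocaine lines have a second rise upstream, with 25.3% and 24.1% between 500 and 200 bp. Median peak width is 734, 727, 110 and 107 bp in the 4 lists in that order, so the middles are of peaks of unlike width.

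The fourth comparison, CC against SC, sets mice that received cocaine last with and without a history side by side. The strongest SC promoter peaks with none in CC were those of the zinc finger gene Bnc2 (18.3, chromosome 4, 84545205 to 84545923), Erich2 (18.2), the lymphoid factor Ikzf3 (18.2), the retinal ganglion cell factor Pou4f2 (17.9) and the nicotinic receptor subunit Chrna5 (17.7). These 5 had promoter peaks in SS as well and none in CS. Both lists held 3014 genes (23.3% of SC promoter genes). With a promoter peak in SC and none in CC there were 9934 genes, and 380 in the other direction, of which 114 had no overlapping SC peak. The strongest of these were Snord37 (8.57), the ubiquitin enzyme Ube2t (6.32, chromosome 1, 134962713 to 134962795), the mitotic kinase Pbk (6.04), the copper transporter Slc31a1 (5.98) and Susd3 (5.80), and all but Snord37 had a promoter peak in SS. Of SC peaks 15.9% overlapped a CC peak (15.4 to 16.4%), and 88.2% of CC peaks overlapped an SC peak (87.2 to 89.1%). At −log10 q of at least 5 the first share was 2.97%.

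The fifth comparison, CC against CS, concerns cocaine against saline after the same history, between lists of similar peak width (median 107 and 110 bp). The 1778 genes with a promoter peak in both were 52.4% of the CC and 41.2% of the CS promoter genes. In CS and absent from CC were 2542 genes, led by Mcmbp (8.03, chromosome 7, 128700022 to 128700096), Rnf14 (7.94), the 5S rRNA transcription factor Gtf3a (7.37), Ranbp9 (7.08) and the ubiquitin ligase Ubr1 (7.03). In CC and absent from CS were 1616 genes, led by Sidt1 (7.47, chromosome 16, 44332512 to 44332764), Zc3h15 (7.42), the importin Ipo9 (7.25), the tubulin folding cofactor Tbce (6.89) and Cdk5rap1 (6.89). These 10 genes all had promoter peaks in both SS and SC. At Mcmbp the SS peak (128739666 to 128740662) and the SC peak (128739698 to 128740837) lay at another start site than the CS peak. Of the fixed lists, Anp32e and Fosb were found in CS and not CC, and Gnal, Nr4a2, Ino80 and H2afv in CC and not CS.

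Only 25.2% of CS peaks overlapped a CC peak (24.2 to 26.3%) and 33.4% of CC peaks overlapped a CS peak (32.1 to 34.8%). Overlap was 22.3% for CS peaks with a fold enrichment under 6, 44.8% between 6 and 8, and 89.1% from 8 upward, where 156 of 175 peaks were shared. Strong CS peaks were mostly not promoter peaks, by a count made after the data were seen. Of the 100 strongest, 9 lay within 1000 bp of a TSS, 42 were intergenic and 10 lay on contigs outside the chromosomes. Of these 100 peaks, 90 overlapped one of the 100 strongest CC peaks. Of SS peaks 2105 were overlapped in both lists, where 788 would be if the lists were independent and 1324 if they were independent within groups of like strength and width. Counting peaks within 1000 bp as shared brought the share of CS peaks to 45.8%. At −log10 q of at least 5 the genes in CS only numbered 534 and those in CC only 422.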

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

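The tests of read depth, of a uniformly lower profile, of calling settings, of sex make-up, of the background on chromosome X and of open promoters were chosen only after the result was seen.

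Signal outside the chromosomes was flagged because it exceeded that of the saline-saline list, which serves as control. The unplaced contig JH584304.1 carried 95 peaks in CS and 96 in CC, against 30 in SS and 26 in SC. The mitochondrial sequence carried 14 peaks in CS and 14 in CC, against 1 in SS and 6 in SC.

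The CS and CC lists held fewer and narrower peaks than SS and SC. Fewer reads as the whole cause would leave the strongest peaks best held if all lists were called alike. In that case alone they were argued against: 22.8% of the strongest SS group was overlapped in CC, below the 31.4% of the fourth group. A uniformly lower signal or a stricter threshold on the same profile was argued against in that case as well, since 27.6% of the strongest SS group was overlapped in CS, below the 40.8% of the fourth group. These shares were known when both predictions were written, so they are no independent test, and they do not cover lists called with unlike settings. A shorter fragment length or another calling setting cannot be told apart from the cocaine history, because the shortest peak was 69 bp in CS and 67 bp in CC against 321 and 315 bp in SS and SC, along exactly that division. The background level read from the steps of the fold enrichment was 1.99 in CS and 1.76 in CC against 9.34 in SS, as fewer reads would also predict. Of the folds, 24.3% in SS, 41.9% in CS and 29.1% in CC lay on such steps, against 4% by chance. Per bp of the shortest peak the background was 99.1% of SS in CS and 90.2% in CC, a scaling that presumes the shortest peak to follow the fragment length. Fewer reads as a part of the cause were not tested, and a loss of H2A.Z from promoters after a cocaine history stays open as an untested hypothesis.

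X-linked promoters stood out in SC against SS. Whether the animals differed in sex make-up could not be decided. The test presumed that fewer X peaks in SS mean fewer X copies, so that Y-linked promoters would be held there. That premise was not tested, and missing Y-linked promoter peaks could themselves come from another sex make-up. Of 5 Y-linked SC promoter peaks (at 4 genes, fold enrichment 3.10 to 4.66), 0 overlapped an SS peak (upper 95% limit 52.2%). The share was 87.5% for autosomal promoter peaks of the same fold range (lower limit 86.3%). Over its whole length chromosome Y carried 9 peaks in SS and 11 in SC. Extra weak calls in SC were argued against, since SC-only X peaks had a median fold enrichment of 3.98, above the upper quartile of SC-only autosomal peaks (3.50). Another control or local background for 1 of the lists cannot be told apart from an effect of a first cocaine exposure, because no control values were among the data: shared X peaks had a median fold enrichment of 4.26 in SS, below the autosomal range of 4.55 to 5.30, and of 5.69 in SC, within the autosomal range of 5.08 to 5.77.

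Neuronal and signalling lists, without the MAPK and CREB list, were joined after seeing the data. Their 163 genes with an SS promoter peak were held in 9.20% of cases in CS and 8.59% in CC, and 142 housekeeping genes in 36.6% and 21.1%. The MAPK and CREB list left out was held in 20.8% of cases in CS and 12.5% in CC. The low share of the joined lists was not particular to neuronal genes: the 40 developmental transcription factors presumed silent were held in 2.5% and 0% of cases. For the joined lists, narrower SS peaks were argued against, because random sets matched on strength and width were held in 23.4% in CS (percentile 0 for the observed 9.20%) and 18.2% in CC (percentile 0.04). Weak SS peaks were argued against, because among genes above the median SS strength 8.54% of 82 neuronal genes were held in CS, against 29.0% in random sets, and 9.76% against 23.2% in CC. That CS and CC peaks may mark open promoters of broadly used genes rather than H2A.Z cannot be told apart from a loss of H2A.Z at the poorly held promoters: SS fold enrichment predicted overlap in CS with an area under the ROC curve of 0.705, and no accessibility or input values were among the data.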

How the results depend on the processing

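Alternatives that were added after the data were seen are named as such. No paired analysis was possible because each condition has 1 peak list with no values per sample, and leaving out a replicate was not run for the same reason. The order of the lists changed in several values, among them the promoter shares under the stricter threshold, with equal lengths and weighted by width, SS peaks overlapped in CS and CC with equal lengths, and the ROC areas of CS and CC under the stricter threshold and with strength from the q-value. Where a value moved, the cause was not tested, except that cutting all lists to the length of the shortest (4827 peaks) by construction leaves fewer genes. Of the percentiles of gene lists under the alternatives, 273 stayed on their side of the limits, 10 no longer passed them and 8 newly did. Most of the 273 belong to lists that passed no limit in the main setting. Under the stricter threshold no list in CS or CC could fall below the lower limit. Only 2 lists in SC, 3 in CS and 2 in CC had passed a limit, and the 10 come from these. Weak calls limit the CS and CC lists more than the SS and SC lists. In CS and CC 17.8% and 19.6% of peaks reached −log10 q of 5, against 97.7% in SS and 97.9% in SC.

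With only peaks of −log10 q of at least 5, CS held 1143 and CC 947 peaks, at 644 and 532 promoter genes. SS peaks overlapped in SC, CS and CC were then 76.3%, 3.49% and 2.94%, SC peaks overlapped in CC 2.97%, and CS peaks overlapped in CC 32.7%. Promoter shares were 63.3% in SS, 64.4% in SC, 61% in CS and 60.6% in CC, so the higher promoter share of CS and CC was not seen. Promoter genes absent from SS were 53 in CS and 49 in CC, those in CC absent from SC 59, in CS absent from CC 534 and in CC absent from CS 422. The area under the ROC curve was 0.659 for CS and 0.660 for CC. Gene lists below the 2.5 percentile were 1 in SC, 0 in CS and 0 in CC, where the main counts were 0, 3 and 2. The zeros in CS and CC carry no information on the lists: only 4.37% and 3.57% of SS promoter genes were held there, so a list with no member held would lie at 3.05 in CS and 5.23 in CC at the lowest. In the main setting 14 of the 21 lists in CS and 12 in CC could fall below the limit.

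With lists of equal length, SS peaks overlapped in SC, CS and CC were 88.5%, 22.2% and 22.8%, SC peaks overlapped in CC 21.9%, and promoter shares 93.6% in SS and 93.1% in SC. Promoter genes were then 4463 in SS and 4435 in SC. Genes in SS and absent from SC, CS and CC were 607, 3477 and 3433, genes absent from SS 579 in SC, 2417 in CS and 2364 in CC, genes in SC absent from CC 3415 and in CC absent from SC 2374. Gene lists below the 2.5 percentile were 1 in CS and 1 in CC, where 1 and 2 of the 13 lists still tested could fall so low, and 0 lay above the upper limit in SC, where the main count was 2 (voltage-gated channels and the respiratory chain, neither of which could pass it at that length).

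Requiring 50% of the shorter peak gave 74.8% for SS in SC, 19.6% for CS in CC and an area of 0.847 for SC. Counting peaks within 1000 bp gave 78.1%, 22.2% and 17.2% for SS in SC, CS and CC, 17.8% for SC in CC and 45.8% for CS in CC. Strength taken from the q-value gave areas of 0.872, 0.719 and 0.729 for SC, CS and CC. Weighting by width gave promoter shares of 73.5% in SS, 72.8% in SC and 78.9% in CC, and a window of 3000 bp gave 1 gene list below the 2.5 percentile in SC. Among alternatives added later, CS peaks overlapped in CC were 24.1% on chromosomes 1 to 19 and X and 24% on autosomes. Counting overlap as held left 516 genes in SC, 49 in CS and 31 in CC absent from SS and 114 in CC absent from SC, with 2 gene lists below the 2.5 percentile in SC and 5 in CS, and the respiratory chain at 97.2 in SC, under the upper limit.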

Other observations

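The values in this part were chosen after the data were seen. The strongest peaks of CS and CC lay mostly outside promoters. Of the 100 peaks with the highest fold enrichment, 9 lay within 1000 bp of a TSS in CS and 11 in CC, against 86 in SS and 89 in SC. Intergenic sequence held 42 of them in CS and 41 in CC, against 3 and 4, and contigs outside the chromosomes held 10 and 11, against 0 and 0. Of the 100 strongest CS peaks 90 overlapped one of the 100 strongest CC peaks, and 88 overlapped an SS peak. Peaks assigned to the gene Sfi1 numbered 37 in CS and 41 in CC, against 14 in SS and 9 in SC.

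Chromosome X was poorly held in CS and CC. It carried 400 peaks in SS, 515 in SC, 29 in CS and 17 in CC. Of the SS peaks on it 3.50% overlapped a CS peak, against 18.0 to 23.4% on the autosomes, and 2.00% overlapped a CC peak, against 13.9 to 18.0%. These shares were not matched on strength. X peaks shared by SS and SC had a median SS fold enrichment of 4.26, below the autosomal range of 4.55 to 5.30, and the weakest SS groups were overlapped least often. A cocaine history cannot be told apart here from other calling settings for CS and CC.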
